A study of Mus musculus with 4 samples.

How the data were processed

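The series holds 4 single-cell RNA-seq libraries of sorted mouse cells, 1 for each pair of stage (E13.5 fetal liver, adult bone marrow) and Nfe2 genotype (wild type, knockout). Per the labels, each library is a pool: 8 wild-type and 6 knockout embryos, and 2 recipients of each genotype taken at least 4 weeks after transplant. Cells were sorted as LIN (Ter119, B220)- CD41high CD42d+, per the labels. The read length and the GFP gate of the adult sort are given in 2 ways in the labels, and 1 label names another gene than Nfe2, so none of these was used. The values used here are deposited UMI counts per gene and cell, which the authors made with Cell Ranger 2.0 on the mm10 genome, per the submitters' processing notes. Aligner settings, the annotation release and the filters that chose the cells are not given in the sources used here. The deposited annotation gave each cell a cluster number, with numbers shared by both genotypes of a stage, and a class name. All 9594 deposited cells had both.

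Each file held 27998 genes, 65 symbols of which were duplicated, so genes were handled by identifier. Coordinates came from GENCODE release M21 on GRCm38 for 27645 genes, and 353 had none. Library totals were 79820433 and 107352998 UMIs in fetal wild type and knockout and 9777280 and 10348359 in adult wild type and knockout. The lowest cell had 5540, 7397, 2239 and 2756 UMIs, in the same order. The median mitochondrial share was 2.62%, 2.68%, 2.52% and 1.31%. A count of 0 allows up to 3 counts at 95% confidence, which is 0.0376, 0.0279, 0.307 and 0.290 CPM in these libraries, and this floor was used for every bound. The exact interval of such a ratio starts lower than its bound, as at 408-fold for adult Hbb-y, bounded at 502-fold. Cells were thinned to 2000 UMIs with seed 1 where shares of cells with a gene were compared, after which the median number of genes was 1070, 1040, 935 and 939.

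UMIs were summed over the cells of a library, or of a class within it, and divided by the total (CPM). Comparisons were knockout against wild type in each tissue and adult against fetal in each genotype, then the difference of the knockout log2 ratio between tissues. With 1 library per group no test was run and no spread between animals could be computed. Log2 ratios carry exact conditional binomial 95% intervals, counts exact Poisson intervals and shares Clopper-Pearson intervals, all of counting error only. A gene was compared when it had at least 100 UMIs over the 2 libraries and at least 20 CPM in the higher one, and it was counted as apart at 2-fold or more.

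Genes were named by a rule written before any value was seen: the 12 genes apart with the largest lower limit of the fold each way in each comparison, 6 each way inside each class, 6 each way for the tissue difference, up to 4 members of each list with the most UMIs and up to 4 with the largest ratio, and always Nfe2, Nfe2l2, Mafg and Mafk. Predicted genes, clone names, ribosomal protein genes and mitochondrial genes were not ranked, and genes that tell the sex of a pool were kept apart. Lists of 539 genes in all, 33 in number, were fixed at the same time, and 6 of their symbols matched no gene. A list was read by its members at least 1.5-fold apart, its median log2 ratio, and the percentile of that median among 10000 random lists drawn from the same 10 bins of level.

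Inside a tissue, 10 classes or clusters with at least 50 cells in both genotypes were compared. A class lost its deposited name when the top 10 genes of any of its clusters, with a pseudocount of 1 CPM, held more lineage genes of another class than of its own, and its clusters were then compared by number. A cluster with lineage genes of neither kind passed, as adult Macrophage clusters 0 and 2 did. Which lineage genes count for a class was settled after the leading genes of the clusters were seen. The Eosinophil class had no lineage genes of its own in this check, so 1 gene of another class was enough to fail it. The fetal and adult Eosinophil, the Progenitor and the MPP classes were not kept under their names. The fetal Progenitor clusters never had 50 cells in both genotypes, so the genes of that class, the largest, are not reported. The class enters its share, the common weighting of classes and the correlation between tissues inside the class.

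Alternatives were median-of-ratios (DESeq2 1.42.0) and TMM scaling (edgeR 4.0.16), each cell's own CPM, no minimum or a stricter one of 500 UMIs, common class weights (classes with at least 10 cells in both libraries), totals without erythroid, globin and mitochondrial genes, only cells with at least 2000 UMIs, without cells over 10% mitochondrial UMIs, and without doublets. A common class weight is the mean of the shares of a class in both libraries, so large classes still weigh more. Scrublet, with an expected rate of 5%, marked 39 of 9594 cells (0.407%), so it has not worked as doublet removal, and leaving out the 480 cells with the highest 5% of scores in each library was added. Leaving out single clusters was also added after their values were seen. The pipeline was tested on simulated data with 200 genes made different: the 95% intervals covered the true ratio for 94.7% to 95.7% of genes, all 4-fold differences were recovered, and 0 unchanged genes were counted as apart. Those counts were Poisson draws from a profile shared by both libraries, without variation between animals, cells or clusters. The simulation checks the calculation only and cannot tell how often a gene apart between single pools is false. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19 and matplotlib 3.10.9, and R 4.3.3.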

Results

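Megakaryocytes are the marrow and fetal liver cells that release platelets, and Nfe2 codes for the tissue-restricted subunit of NF-E2, a transcription factor that pairs with a small Maf protein and is needed late in their maturation. Single-cell 3' UMI counts were compared between wild-type and Nfe2 knockout mice at a pair of stages, in 4 libraries with 1 library per group. The fetal libraries came from pooled E13.5 livers (8 wild-type and 6 knockout embryos). The adult libraries came from the bone marrow of 2 recipients per genotype, pooled, at least 4 weeks after a transplant of fetal liver cells. Cells had been sorted as LIN (Ter119, B220)- CD41high CD42d+. The fetal libraries held 3165 wild-type and 3418 knockout cells, with medians of 24465 and 30255.5 UMIs and 4678 and 4961 genes per cell. The adult libraries held 1698 and 1313 cells, with medians of 4067.5 and 5905 UMIs and 1363.5 and 1750 genes. With 1 library per group no difference could be checked on replicates, and every 95% interval below holds counting error only. For the adult cells the labels give the sort as GFP-negative in the protocol and GFP-positive in the surface phenotype, so which of donor and recipient they came from is not settled.

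Nfe2 (ENSMUSG00000058794, chromosome 15, 103248212 to 103258403, GRCm38) was counted in all 4 libraries. In fetal liver its level was 153 CPM (150.2 to 156) in wild type and 116 CPM (114 to 118) in knockout, a log2 ratio of -0.40 (-0.43 to -0.36). In adult marrow it was 98.6 CPM (92.5 to 105) and 71.3 CPM (66.3 to 76.7), a log2 ratio of -0.47 (-0.61 to -0.33). At least 1 Nfe2 UMI was found in 92.0% of wild-type and 90.2% of knockout fetal cells and in 37.8% and 36.7% of adult cells, and in 25%, 22.5%, 18.4% and 12.9% once every cell was thinned to 2000 UMIs. Adult B cells, which should lack Nfe2, gave 4 of 127 wild-type cells (3.15%, median 2885 UMIs) and 0 of 51 knockout cells (upper limit 6.98%, median 3817 UMIs), and no fetal class should lack it. The labels do not say which part of Nfe2 was removed. A 3' tag is counted from any transcript that keeps the last exon, so these counts do not test the knockout. Of its partners and relatives, Mafg was lower in fetal knockout cells (41.8 against 79.7 CPM, log2 ratio -0.93) and level in adult knockout cells (0.06). Mafk gave -0.08 and -0.51, and Nfe2l2, which codes for the related factor NRF2, gave -0.28 and 0.25. Inside the deposited Megakaryocyte class the ratio of Mafg was -1.52 in fetal liver and -0.92 in adult marrow, and that of Nfe2 was -0.77 and -0.15 (interval -0.49 to 0.20). With clusters left out after their values were seen, these moved to -1.13 and -0.21 in fetal liver (without clusters 10, 13 and 14) and to -0.41 and -0.10 in adult marrow (without cluster 12).

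Fetal knockout cells had less RNA of Slc6a4, Gp6 and Tbxas1, which platelets use, and more RNA of embryonic globins and Alas2. The serotonin transporter Slc6a4, which loads serotonin for storage in dense granules, was far lower, and so were the collagen receptor gene Gp6 and the thromboxane synthase gene Tbxas1. Itga2b (CD41) and Pf4 were at or above their wild-type level. Embryonic Hbb-y, Hbb-bh1 and Hba-x and the heme synthesis gene Alas2, which belong to red cells, were all higher in the knockout. Of 5143 genes compared, 129 were at least 2-fold apart, 48 higher and 81 lower in the knockout.

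Slc6a4 (ENSMUSG00000020838, chromosome 11, 76998603 to 77032340) was furthest below wild type, at 0.149 against 26.6 CPM (knockout against wild type, here and below), 178-fold lower (109.6 to 313). Gp6 (ENSMUSG00000078810, chromosome 7, 4363965 to 4397744) was at 2.56 against 53.1 CPM (log2 ratio -4.37), and Tbxas1 (ENSMUSG00000029925, chromosome 6, 38875404 to 39084585) at 5.50 against 101 CPM (-4.21). Also lower were Slamf1 (2.56 against 30.9 CPM, -3.59), the inhibitory receptor G6b (5.78 against 62.6 CPM, -3.44), the podoplanin receptor Clec1b (65.1 against 322 CPM, -2.31) and the integrin-linked actin adaptor Parvb (23.6 against 121 CPM, -2.36). The other lower genes named by the size rule had log2 ratios of -3.09 (Homer2), -2.90 (Cst7), -2.67 (Mest), -2.52 (Aqp1) and -2.46 (Gadd45a). Highest above wild type was Prrt4 (ENSMUSG00000079654, chromosome 6, 29169232 to 29179584), at 59.3 against 0.213 CPM, 278-fold higher (174 to 478). Alas2 (93.9 against 3.83 CPM, 4.61), Hbb-bh1 (140.1 against 8.18 CPM, 4.10), Hbb-y (1169 against 88.8 CPM, 3.72), Hba-x (175 against 18.6 CPM, 3.24) and adult-type Hbb-bt (1882 against 384 CPM, 2.29) followed. The Duffy receptor gene Ackr1 (3.43), Pdzk1ip1 (3.12), the chemokine Cxcl5 (125 against 18.1 CPM, 2.79), Ddah1 (2.58), Ddc (2.37) and the B-lineage factor Pou2f2 (2.29) were higher as well. Median-of-ratios scaling moved all fetal ratios up by 0.11 and gave 58 genes higher and 67 lower.

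Much of the fetal globin signal sat in cluster 7, which held 420 knockout cells and no wild-type cell, was deposited as Erythrocyte, and was chosen for exclusion after its values were seen. Without it, 118 genes were at least 2-fold apart (29 higher and 89 lower). The log2 ratios were then 2.88 for Alas2, 1.76 for Hbb-y, 2.62 for Hbb-bh1, 1.07 for Hba-x, 1.06 for Hbb-bt and 5.80 for Prrt4. With common class weights (the mean of the shares of a class in both libraries), Hbb-bt was level (0.09) and Alas2 at 2.35. The Erythrocyte class held 29 wild-type cells, all of cluster 12, while its knockout cells were mostly of cluster 7. That weighting therefore does not pair like cells. Without clusters 7 and 10 together (227 of the 231 cells of cluster 10 were wild-type), 92 genes were apart, 31 higher and 61 lower. Slc6a4 was then at -4.72, while Mest (-0.28) and Gadd45a (-0.64) were no longer 2-fold lower. The fetal libraries shared few clusters: clusters 0, 2, 4, 5 and 7 were almost all knockout and clusters 1, 3, 6, 8, 9 and 10 almost all wild-type. Genotypes were therefore paired by class where the class name passed the marker check and both had at least 50 cells, which left the Megakaryocyte class, and by cluster number in cluster 11.

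**Figure D1:**
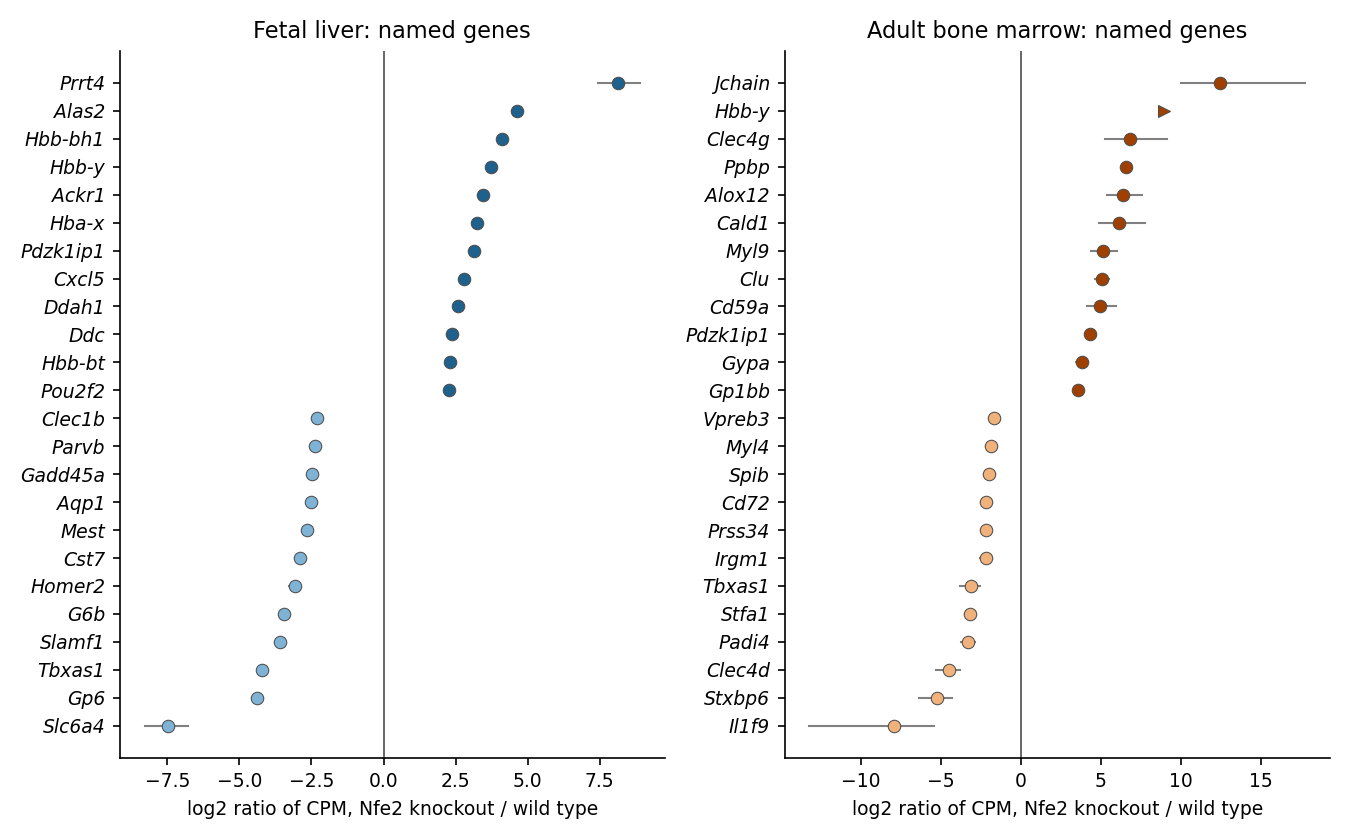
Log2 ratio of knockout to wild type for the 12 higher and 12 lower genes named by the size rule in each tissue, with 95% counting intervals. In fetal liver Slc6a4 (-7.48) was lowest and Prrt4 (8.12) highest. The triangle marks Hbb-y in adult marrow, set at the floor of its wild-type count of 0, and its interval starts lower.

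Gene lists fixed before the data were examined were read as the count of genes at least 1.5-fold apart, the median log2 ratio, and the percentile of that median among 10000 random lists matched for level. In fetal liver the megakaryocyte surface list was split (2 higher and 4 lower of 19, median 0.06, percentile 97.3): Gp1bb (0.75) was higher, Gp9 (0.41) and Itga2b (0.42) were within 1.5-fold, and P2ry12 (0.149 against 8.69 CPM), Gp6 and Clec1b were lower. The alpha-granule list gave 6 higher and 3 lower of 22, median 0.28, percentile 100, with Ppbp at 4759.8 against 1184 CPM and Pf4 at 20642 against 12588 CPM. Dense-granule genes gave 0 higher and 2 lower of 18, median -0.21, percentile 5.82, proplatelet cytoskeleton genes 0 higher and 3 lower of 25, median -0.04, percentile 31.8 and platelet signalling genes 1 higher and 4 lower of 26, median -0.13, percentile 5.74. In the cytoskeleton list the tubulins were the lower ones, Tuba4a (169.6 against 608 CPM, -1.84), Tubb1 (a trace gene here, 0.95 against 3.91 CPM, -2.04) and Tuba8 (-0.78), while Actb (0.29) and Tmsb4x (0.40) were not lower. Of 5 reported NF-E2 targets, Tbxas1 and Tubb1 were lower and Slc35d3 (0.12), Lims1 (599.5 against 601 CPM) and Rab27b (-0.23) were within 1.5-fold. Megakaryocyte transcription factors gave 0 higher and 2 lower of 17, median -0.03, percentile 64.0, with Gata2 (18.6 against 69.0 CPM, -1.89) apart from Gata1 (0.09). NF-E2 partners and relatives gave 0 higher and 1 lower of 8, median -0.26, percentile 4.51.

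Of the fetal lists of other lineages, stem and progenitor genes gave 1 higher and 5 lower of 10, median -0.62, percentile 0.0100 (Cd48 -2.19, Myb -1.24). Mast and basophil genes were lower (0 higher and 8 lower of 8, median -1.46, percentile 0; Cpa3 0.913 against 7.53 CPM), and neutrophil granule genes gave 0 higher and 7 lower of 15, median -0.36, percentile 0.0800 (Mpo 29.0 against 124 CPM, Prtn3 -1.57). Hepatocyte genes were lower at trace levels (0 higher and 7 lower of 7, median -1.94, percentile 0; Alb 0.615 against 4.03 CPM). Erythroid genes gave 7 higher and 1 lower of 19, median 0.29, percentile 100 and embryonic globins 3 higher and 0 lower of 3, median 3.72, percentile 100, but Hbb-bs was lower (298 against 594 CPM, -1.0). Without cluster 7 the erythroid list gave 4 higher and 2 lower. Immediate-early and heat-shock genes gave 0 higher and 8 lower of 15, median -0.60, percentile 0 (Fos -1.55, Dusp1 -1.63). S-phase genes gave 0 higher and 2 lower of 42, median -0.34, percentile 0, G2/M genes 0 higher and 3 lower of 51, median -0.27, percentile 0, endomitosis and cytokinesis genes 1 higher and 2 lower of 15, median -0.27, percentile 0.560, fetal growth genes 1 higher and 6 lower of 13, median -0.55, percentile 0 and MHC class I genes 0 higher and 4 lower of 9, median -0.51, percentile 0.02 (Psmb8 -1.88). NRF2 antioxidant genes went both ways (3 higher and 6 lower of 19, median -0.14, percentile 14.1; Srxn1 -1.53, Hmox1 1.62), as did macrophage genes (4 higher and 6 lower of 14, median -0.38, percentile 7.27; C1qb 2.95, Irf8 -1.87) and interferon genes (3 higher and 2 lower of 13, median 0.14, percentile 98.8; Isg15 33.1 against 8.49 CPM, Rsad2 -2.03). Glycolysis (0 higher and 1 lower of 15, median 0.20, percentile 100), cholesterol synthesis (0 higher and 0 lower of 15, median 0.03, percentile 95.5), unfolded-protein (0 higher and 1 lower of 14, median -0.01, percentile 70.6), p53 and apoptosis (3 higher and 1 lower of 17, median -0.03, percentile 80.2) and mitochondrial genome lists (0 higher and 0 lower of 12, median 0.01, percentile 71.0) had at most 4 members apart. Endothelial (3 higher and 0 lower of 8, median 0.43, percentile 99.93), stromal (3 higher and 1 lower of 6, median 0.37, percentile 97.8) and B-cell lists (1 higher and 0 lower of 3, median 0.24, percentile 92.7; Ebf1 9.50 against 0.589 CPM, 4.01) were at or above level, and 1 T and NK gene, Nkg7, was measured (-0.48).

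Within the cells deposited as fetal megakaryocytes, the knockout had less RNA of Slc6a4, P2ry12 and Gp6 and of most genes of the G2/M list. P2ry12, the ADP receptor that clopidogrel blocks, was far lower. The chemokine Ppbp, an alpha-granule cargo, was higher, but the alpha-granule list went both ways (4 higher and 5 lower of 21, median -0.02, percentile 55.5), and surface genes gave 0 higher and 5 lower of 19, median -0.17, percentile 2.88. Of 5115 genes compared in this class, 62 were higher and 187 lower. With each cell's own CPM more genes were apart, most of them lower (counts given below). The class was filled by different clusters in each genotype (knockout: 626 of 718 cells in cluster 4; wild type: 543 and 227 of 805 cells in clusters 6 and 10), with median depths of 29330 and 24113 UMIs. These ratios also hold what set the clusters apart. Wild-type cluster 10, whose top genes include Slc6a4 and P2ry12, had a median Malat1 of 124488 CPM at 8804 UMIs. In wild-type cluster 6 these were 7229 CPM and 29320 UMIs. Knockout cluster 7, closest to wild-type cluster 10 in its mean profile, lay outside the class as Erythrocyte.

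The lowest genes of the class were Slc6a4 (0.360 against 103 CPM, -8.16), P2ry12 (0.225 against 33.5 CPM, -7.22), Dusp14 (-5.64), Slamf1 (-5.41), Tbxas1 (7.12 against 209 CPM, -4.87) and Gp6 (6.26 against 176 CPM, -4.81). The highest were Prrt4 (41.0 against 0.665 CPM, 5.95), Alas2 (81.8 against 2.61 CPM, 4.97), Aard (4.76), the metallothionein Mt2 (76.0 against 5.88 CPM, 3.69), the erythroid surface gene Gypa (3.03) and Ddah1 (3.01). Of 50 G2/M genes measured, 0 were higher and 41 lower (median -0.92, percentile 0), including Nusap1 (19.8 against 61.5 CPM, -1.63), Ckap2l (-1.50), Ube2c (157 against 389.9 CPM, -1.32) and Kif11 (-1.46). The endomitosis and cytokinesis list gave 2 higher and 8 lower of 14, median -1.09, percentile 0, with Prc1 (-1.61), Incenp (-1.25) and Plk1 (-1.18) lower. The S-phase list had only 2 of 42 genes lower, but its median was low as well (-0.31, percentile 0.02). Without clusters 10, 13 and 14, a step added after the values were seen, 41 of 50 G2/M genes were again lower (median -1.0). Cells with mitotic top genes were deposited as Progenitor, outside this class, in both genotypes, so the class boundary can set these ratios. After the values were seen, 815 wild-type cells in cluster 1 (Pf4 9356 CPM) and 773 and 561 knockout cells in clusters 2 (12579 CPM) and 5 (24532 CPM) were picked out as such. Cluster 5, near the class in Pf4, held 16.4% of knockout and 0.19% of wild-type cells. With clusters 10, 13 and 14 left out, the lowest genes lay closer to wild type: P2ry12 at -3.07, Dusp14 at -2.22 and Slc6a4 at -5.01, with Tbxas1 at -4.61 and Gp6 at -4.34. Proplatelet cytoskeleton genes gave 0 higher and 6 lower of 25, median -0.31, percentile 0 and platelet signalling genes 0 higher and 7 lower of 26, median -0.28, percentile 0.0700, led by Tuba4a (240.2 against 1012 CPM, -2.07) and Tubb1 (-2.79). Clec1b (98.7 against 782 CPM, -2.99) and Gata2 (6.53 against 81.5 CPM, -3.64) were lower. Itga2b was level (0.07), and Ppbp was at 11544 against 4162 CPM (1.47). Cholesterol synthesis genes gave 3 higher and 0 lower of 15, median 0.35, percentile 100, and Cdkn1a, a cell-cycle inhibitor of the p53 list, was at 74.2 against 27.8 CPM (1.42).

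**Figure D2:**
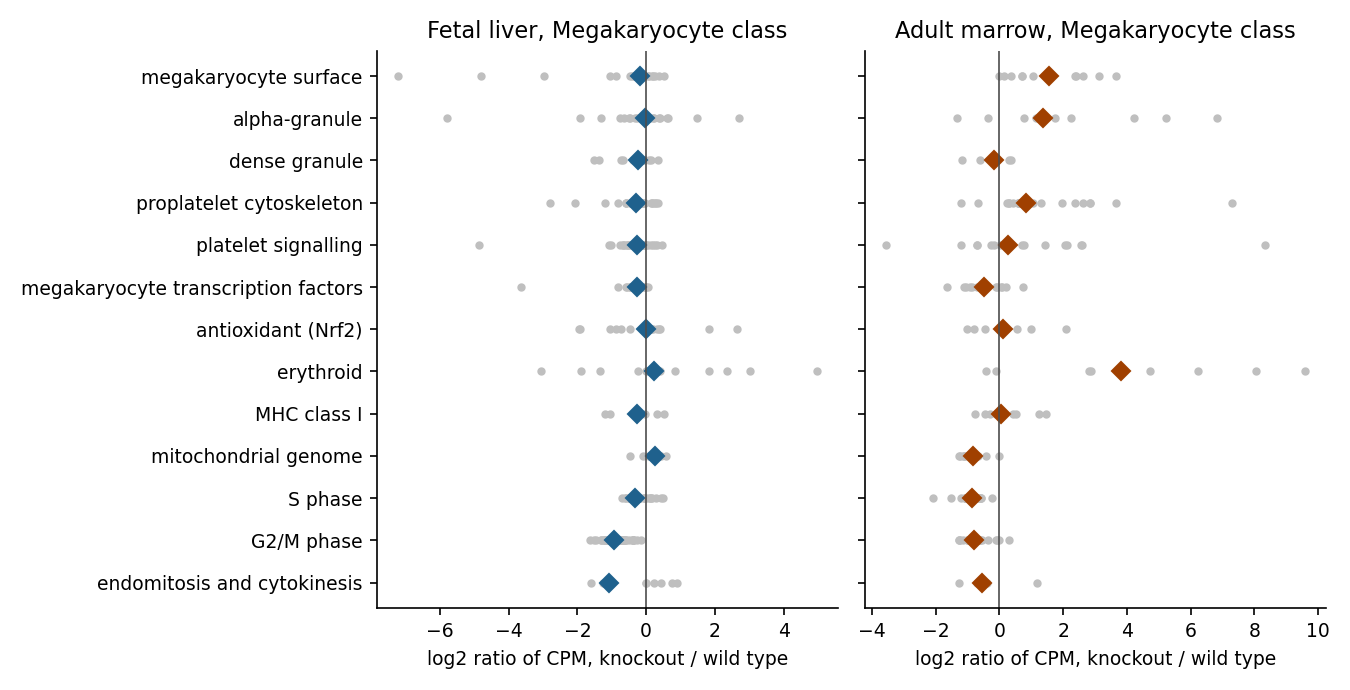
Log2 ratios of knockout to wild type for the genes of 13 lists inside the Megakaryocyte class (grey) and their medians (diamonds). In the fetal class the G2/M median was -0.92; in the adult class the megakaryocyte surface median was 1.55.

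After the CD41high CD42d+ sort, the deposited Megakaryocyte class held 25.4% (23.9 to 27) of wild-type and 21.0% (19.7 to 22.4) of knockout fetal cells. The Progenitor class held 70.1% and 63.3% (median depths of 24676.5 and 33631.5 UMIs). It failed the marker check through 1 of its 7 clusters, cluster 5, which had 1 megakaryocyte gene among its top genes. The Erythrocyte class held 0.916% and 13.7%, but that difference lay in cluster 7, since cluster 12 held 29 and 49 cells. Cluster 7 made up 12.3% of knockout cells, with Itga2b at 4455 CPM, Pf4 at 29762 CPM and Hbb-bs at 445 CPM. Counted with the megakaryocytes, it would put their knockout share above the wild-type one, so the direction rests on the deposited names. In fetal cluster 11, the cells deposited as Eosinophil (67 knockout and 113 wild-type), 189 of 4331 genes were higher and 66 lower in the knockout. Prrt4 (151 and 0 UMIs in knockout and wild type, at least 94.4-fold higher), Meg3 (137 and 0 UMIs, at least 85.6-fold), Alas2 (3 wild-type UMIs, 7.54, interval 5.98 to 9.83), Hbb-bt (4.89), Ppbp (5047 against 206 CPM, 4.62) and Hbb-bs (4.51) led the higher genes. The mast and basophil genes Prss34 (0 and 100 UMIs, at least 17.8-fold lower) and Cpa3 (27.3 against 202 CPM, -2.89) led the lower ones, with Hist1h2ap (-2.23), Slc25a12 (-2.59), Dusp1 (-2.39) and Uba52 (-2.02). Inside this cluster megakaryocyte surface genes gave 11 higher and 0 lower of 13, median 2.08, percentile 100, alpha-granule genes 9 higher and 1 lower of 11, median 2.29, percentile 100 and erythroid genes 8 higher and 0 lower of 8, median 3.23, percentile 100. Neutrophil granule genes gave 7 higher and 4 lower of 15, median 0.35, percentile 99.98, while over all fetal cells 0 were higher and 7 lower. The cluster made up 1.96% of knockout and 3.57% of wild-type cells. The cluster failed the marker check, which held no eosinophil genes, and is led by neutrophil granule genes. S100a8 was found in 52.2% of its knockout and 44.2% of its wild-type cells, and Pf4 in 100% and 99.1%. Doublets and RNA free in the droplets are not excluded.

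In adult marrow the sorted cells were mostly granulocytes, macrophages and their progenitors by deposited name, and the knockout library carried more RNA of several megakaryocyte and platelet genes than the wild-type library. Ppbp and Pf4 code for platelet alpha-granule chemokines, Gp1bb for a subunit of the von Willebrand factor receptor, and Alox12 for platelet lipoxygenase, and all were higher. The embryonic globin Hbb-y, not counted in wild-type adult cells, was present in the knockout. B-lymphoid genes such as Vpreb3 and basophil genes such as Prss34 were lower. Of 4824 genes compared, 166 were at least 2-fold apart, 105 higher and 61 lower.

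Hbb-y (ENSMUSG00000052187, chromosome 7, 103851749 to 103853216) had 1595 knockout UMIs and 0 wild-type UMIs (154 CPM, at least 502-fold higher against a floor of 3 counts, with an exact interval from 408-fold). Ppbp (ENSMUSG00000029372, chromosome 5, 90768518 to 90770063) was at 2219.8 against 23.8 CPM (6.54), and Alox12 (ENSMUSG00000000320, chromosome 11, 70241457 to 70255353) at 67.4 against 0.818 CPM (6.36, interval 5.38 to 7.58). Other higher genes were Clu (159.7 against 4.81 CPM, 5.05), the smooth-muscle myosin light chain Myl9 (50.1 against 1.43 CPM, 5.13), the actin-binding Cald1 (6.13), Clec4g (35.1 CPM, 3 wild-type UMIs, 6.84, interval 5.28 to 9.12), Cd59a (4.95), Pdzk1ip1 (185 against 9.31 CPM, 4.31), Gp1bb (557 against 46.2 CPM, 3.59) and Gypa (88.8 against 6.34 CPM, 3.81). Jchain, which joins immunoglobulin chains in plasma cells, was at 581 CPM with 1 wild-type UMI (12.47, interval 9.99 to 17.78). Of its knockout UMIs, 5925 of 6011 came from 51 B cells. Lower genes included Il1f9 (0.0966 against 23.7 CPM, 1 knockout UMI, -7.94, interval -13.25 to -5.45), Stxbp6 (-5.24), the C-type lectin Clec4d (1.55 against 35.4 CPM, -4.52), Padi4 (5.22 against 51.4 CPM, -3.30), Stfa1 (10.2 against 93.0 CPM, -3.18) and Irgm1 (-2.17). Tbxas1 was lower as in fetal liver (2.42 against 21.4 CPM, -3.15). Prss34 (107 against 479.8 CPM, -2.17), Vpreb3 (86.7 against 277 CPM, -1.67), Spib (-1.97), Cd72 (-2.16) and Myl4 (-1.90) completed the named set.

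The higher megakaryocyte genes rested largely on cluster 12, which held 113 knockout cells and no wild-type cell and was set aside only after its values were seen. Without it, 133 genes were at least 2-fold apart (70 higher and 63 lower). The ratios were then 2.23 for Ppbp, 3.01 for Alox12, 2.16 for Clu, 0.64 for Gp1bb, 0.54 for Pdzk1ip1 and 2.67 for Gypa, and at least 4.31 for Hbb-y, still without a wild-type UMI. Ppbp was also counted outside the class: it was at 33.7 to 321 CPM in every other adult knockout class and at 0 to 19.7 CPM in the wild-type ones. With common class weights, Vpreb3 was at -0.66 and Spib at -0.97. The Basophil class, with 15 wild-type and 5 knockout cells, was too small for that weighting, so it does not bear on Prss34.

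**Figure D3:**
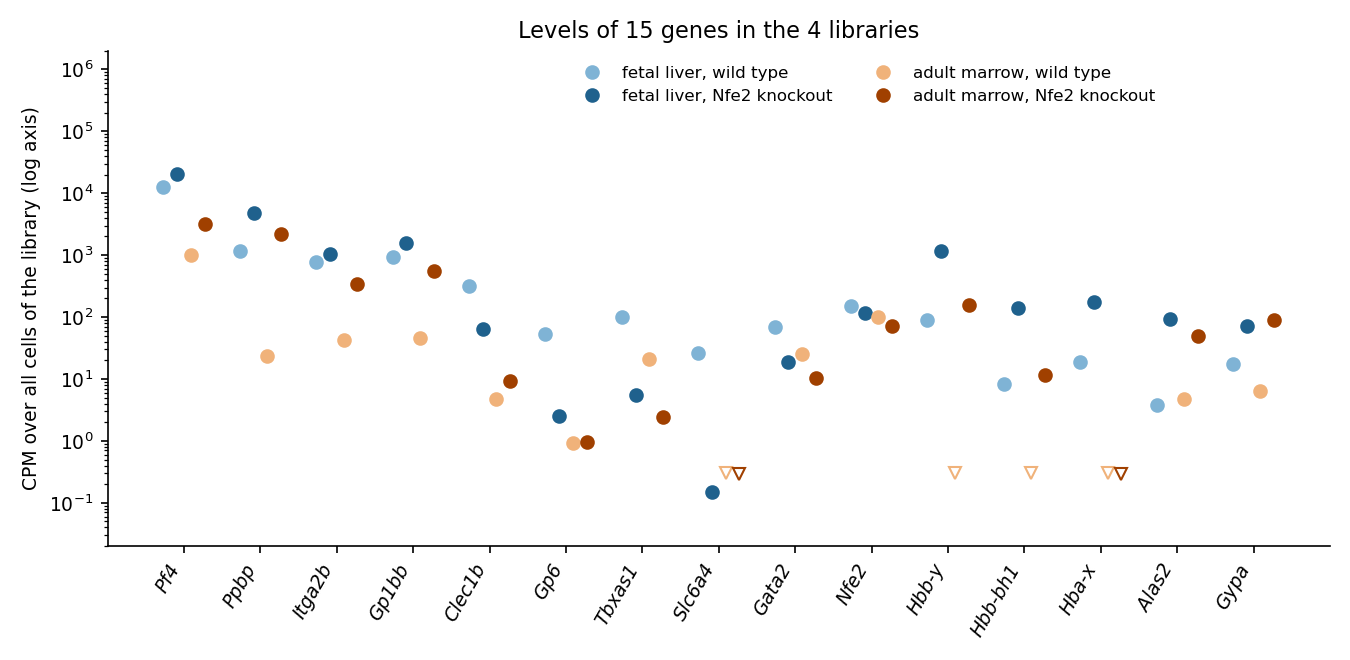
CPM of 15 genes in the 4 libraries, picked after their values were seen to show both directions; open triangles mark 0 UMIs, drawn at the floor of 3 counts. Slc6a4 was at 26.6 CPM in fetal wild type and 0.149 CPM in fetal knockout, and Ppbp at 23.8 and 2219.8 CPM in adult marrow.

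Adult lists put the surface receptors of megakaryocytes higher (8 higher and 0 lower of 13, median 0.96, percentile 100; Itga2b 345 against 43.0 CPM, Gp9 2.34, Treml1 2.52). This turned without cluster 12 (2 higher and 4 lower of 11, median -0.36). Alpha-granule genes gave 7 higher and 3 lower of 15, median 0.56, percentile 100 (Pf4 3186 against 1012 CPM, 1.65), dense-granule genes 2 higher and 0 lower of 16, median 0.17, percentile 91.9, proplatelet cytoskeleton genes 5 higher and 1 lower of 24, median 0.27, percentile 99.91 and platelet signalling genes 9 higher and 1 lower of 25, median 0.33, percentile 99.92. Reported NF-E2 targets gave 0 higher and 1 lower of 4, median 0.06, percentile 57.6, partners and relatives 0 higher and 1 lower of 8, median 0.00, percentile 38.4, and megakaryocyte transcription factors 1 higher and 3 lower of 17, median -0.14, percentile 2.48, with Gata2 (10.3 against 25.6 CPM, -1.31) and Meis1 (-1.53) lower. Erythroid genes were higher (12 higher and 0 lower of 13, median 1.75, percentile 100; Alas2 49.9 against 4.81 CPM, Hbb-bs 3286 against 600.2 CPM, Hba-a1 2.62). Without cluster 12 they gave 11 higher and 0 lower of 12. The embryonic globins Hbb-y and Hbb-bh1 (11.7 against 0 CPM, at least 38.1-fold) were the 2 measured of their list. All 9 B-cell genes measured were lower (0 higher and 9 lower of 9, median -1.57, percentile 0; Cd79a 64.7 against 194 CPM, Ebf1 -1.62, Pax5 -1.59). Mast and basophil genes gave 0 higher and 5 lower of 8, median -0.74, percentile 0 (Mcpt8 119.8 against 323 CPM). Mitochondrial genome transcripts were lower (0 higher and 9 lower of 12, median -0.68, percentile 0; mt-Nd2 283 against 589 CPM). Macrophage and antigen-presentation genes gave 5 higher and 0 lower of 12, median 0.32, percentile 99.8 (H2-Ab1 371 against 96.3 CPM, Cd74 1.28), and neutrophil genes were near level (1 higher and 1 lower of 15, median 0.13, percentile 90.9) except Retnlg (1872 against 4574 CPM, -1.29).

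Among cell-state lists in adult marrow, cholesterol synthesis genes gave 5 higher and 0 lower of 14, median 0.54, percentile 100 (Fdps 155 against 90.5 CPM), and endomitosis and cytokinesis genes 3 higher and 0 lower of 14, median 0.42, percentile 100 (Kif23 0.74). S-phase (1 higher and 0 lower of 42, median 0.15, percentile 96.9) and G2/M genes (5 higher and 0 lower of 51, median 0.10, percentile 88.3) were near level by their medians, as were NRF2 antioxidant (0 higher and 0 lower of 15, median -0.08, percentile 7.50), interferon (1 higher and 0 lower of 15, median -0.00, percentile 36.8) and immediate-early genes (1 higher and 1 lower of 10, median 0.13, percentile 76.6). The same held for unfolded-protein (2 higher and 1 lower of 13, median 0.06, percentile 60.3), p53 and apoptosis (1 higher and 1 lower of 13, median 0.03, percentile 47.6), glycolysis (1 higher and 0 lower of 15, median 0.16, percentile 91.6), MHC class I (0 higher and 0 lower of 10, median 0.11, percentile 76.5) and stem and progenitor lists (3 higher and 3 lower of 12, median -0.09, percentile 11.3; Kit -0.76, Cd34 0.94). T and NK genes gave 3 higher and 1 lower of 5, median 0.91, percentile 100 (Gzma 1.16 against 9.21 CPM, Cd3g 1.5). Lists with 1 or 2 genes measured were hepatocyte (Trf 0.34), endothelial (Egfl7 -1.25), stromal (Lepr 1.27, Acta2 -3.68) and fetal growth (Igf2bp3 0.67).

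Cells deposited as adult megakaryocytes had, in the knockout, more RNA of most alpha-granule and proplatelet cytoskeleton genes measured, more Hbb-bt and Gypa, and less RNA of most S-phase genes. Wild-type cells of the class had little Ppbp, a marker of late megakaryocytes, and no Hbb-y. Of 2872 genes compared, 294 were higher and 227 lower, with 113 of the 147 knockout cells in cluster 12 and all 170 wild-type cells in cluster 6 (median 5582 and 3591 UMIs). Within cluster 6 alone, 34 knockout cells against 170, 38 genes were higher and 28 lower. The depth gap was wide there (medians of 16180 knockout and 3591 wild-type UMIs), and it enters every value of this class without cluster 12. Median-of-ratios scaling moved the ratios of this class up by 0.26, and under it 429 genes were higher and 74 lower. With each cell's own CPM, 367 were higher and 1030 lower. Signs of RNA quality moved with these ratios. The median of nuclear Malat1 was 0 CPM in cluster 12 and 7846 CPM in knockout cells of cluster 6. Mitochondrial genome transcripts of the class gave 0 higher and 9 lower of 11, median -0.83, percentile 0.41.

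Hbb-bt (8660.1 against 11.3 CPM, 9.59), Hbb-y (1540 and 0 UMIs, at least 506-fold higher), Ppbp (17647 against 155 CPM, 6.83), Alox12 (516 CPM, 2 wild-type UMIs, 8.32, interval 6.47 to 11.37), Clec4g (320 and 0 UMIs, at least 105-fold) and Gypa (427 CPM, 2 wild-type UMIs, 8.05, interval 6.19 to 11.10) were the highest. Without cluster 12, Hbb-bt was at 2.66, Ppbp at 1.98 and Alox12 at 4.21. Gypa was then at 3.37 (16.6 against 1.61 CPM, with 2 wild-type UMIs), and the lower bounds were 1.46 for Hbb-y and 2.04 for Clec4g. These values rest on few UMIs, and the exact intervals start lower than the bounds. Hbb-y was at 6.64 CPM in the 34 knockout cells, inside its range of 0 to 9.50 CPM over the other adult knockout classes. Igfbp4 (9.51 against 118 CPM, -3.64), Tbxas1 (7.14 against 83.7 CPM, -3.55), Cd63 (-2.36), Glipr1 (-2.47), Apoe (74.5 against 282 CPM, -1.92) and Chchd10 (-1.96) were the lowest. Surface receptors (10 higher and 0 lower of 13, median 1.55, percentile 100), alpha-granule genes (9 higher and 1 lower of 11, median 1.36, percentile 100; F13a1 119.7 against 6.44 CPM) and proplatelet cytoskeleton genes (16 higher and 2 lower of 23, median 0.82, percentile 100; Tmsb4x 1.98, Gsn 386 against 30.6 CPM, Tpm4 2.85) were higher. S-phase (0 higher and 23 lower of 26, median -0.87, percentile 0; Tipin -1.52), G2/M (0 higher and 21 lower of 27, median -0.79, percentile 0.0100; Hmgb2 -0.94) and stem and progenitor genes (1 higher and 5 lower of 7, median -0.99, percentile 0.0600; Myb -1.47, Myc -1.27) were lower. Without cluster 12 the S-phase median was -0.01, the G2/M median -0.04, and the surface median 0.50. The class made up 10.0% (8.62 to 11.5) of wild-type and 11.2% (9.54 to 13) of knockout cells.

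In the adult macrophage class, pooled over 3 clusters, the knockout had more of the myeloid factor Cebpb and less of Hpgd and Fabp5. Cebpb drives monocyte and granulocyte maturation, Hpgd breaks down prostaglandins, and Fabp5 carries fatty acids. Of 4767 genes compared in 403 knockout and 421 wild-type cells (median depths of 6935 and 5356 UMIs), 182 were higher and 40 lower. Mitochondrial genome transcripts gave 0 higher and 7 lower of 11, median -0.63, percentile 0. Clusters 0, 2 and 9 held 189, 156 and 58 of the knockout cells and 218, 129 and 74 of the wild-type cells, and cluster 2, whose top genes include mitotic ones, was the larger in the knockout. Cebpb was at 1772 against 191 CPM (3.21) and Cdk2ap1 at 84.5 against 14 CPM (2.60). Ppbp (3.56), Gp1bb (3.91), Itga2b (3.80) and Hbb-bt (3.09) were also higher, with Ppbp at 82.2 CPM, inside its range over the other classes of that library. Stxbp6 (0.975 against 86.1 CPM, 3 knockout UMIs, -6.47, interval -8.75 to -4.90), Hpgd (-4.19), Fabp5 (21.4 against 186 CPM, -3.12), Mgst1 (126 against 729 CPM, -2.53), Tnfaip2 (-2.49) and Nptn (-2.32) were lower. S-phase genes were higher (20 higher and 0 lower of 31, median 0.69, percentile 100), G2/M genes gave 23 higher and 0 lower of 48, median 0.54, percentile 100, and median-of-ratios scaling moved the ratios of the class by -0.12, from 82.0% to 66.2% higher among genes apart.

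Cebpb was higher as well in clusters 1 (365 against 52.7 CPM, 2.79) and 4 (964 against 124 CPM, 2.96), deposited as Progenitor, and in cluster 8, deposited as Eosinophil (293 against 29.6 CPM, 3.31). In cluster 1 the other leading genes were Gdf3 (3.04), Cdk2ap1 (2.85), Alyref (2.36), Ube2m (2.57) and Taf10 (2.35), against Serpina3g (-3.43), Retnlg (-2.62), Ltf (-2.49), Ccl6 (-2.54), Ngp (-1.96) and Hba-a1 (-2.52). The depth gap was wide there (medians of 20837 knockout and 3419.5 wild-type UMIs in cluster 1, 14216 and 3316 in cluster 4). In cluster 1, 69 genes were higher and 38 lower of 3065, which median-of-ratios scaling took from 64.5% to 49.5% higher. In cluster 4, 70 were higher and 19 lower of 2343 (78.7% to 67.5% higher under that scaling). There, Alyref (2.56), Taf10 (2.41), Pitpna (2.20), Abhd17a (2.56) and Ube2m (2.31) led the higher genes and Mgst1 (-2.11), Retnlg (-2.01), Nptn (-2.40), Ngp (-1.87), Camp (-1.87) and Ltf (-2.19) the lower. Mitochondrial genome transcripts gave 0 higher and 10 lower of 11, median -1.05, percentile 0 in cluster 1 and 0 higher and 9 lower of 11, median -0.74, percentile 0 in cluster 4. Cluster 8 had 17 higher and 10 lower of 1241, led by Mrpl9 (1950.1 against 17.8 CPM, 6.78), Alyref (2.59), Gadd45g (2.22), Ppp2ca (1.81) and Gnai2 (1.40) against Stfa1 (-3.58), Ly6e (-2.57), Retnlg (-2.44), Crip1 (-1.65), Lgals1 (-1.35) and S100a6 (-1.17). Without the 5% of cells with the highest Scrublet score, a step chosen after the values were seen, 12 genes were higher and 2 lower there and Gadd45g was at -0.49. Cluster 3, also deposited as Eosinophil, had 14 higher and 3 lower of 824. The adult globins led (Hbb-bs 2139 against 16.6 CPM, Hba-a1 6.76, Hba-a2 6.44, Hbb-bt 467 and 0 UMIs in knockout and wild type, at least 107-fold), then Pitpna (2.09) and Gnai2 (1.30), while Retnlg (-1.68), Cd63 (-1.12) and Tmcc1 (-1.02) were lower.

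The adult neutrophil class was pooled over clusters 5 and 7, which held 63 and 119 of its knockout cells and 156 and 83 of its wild-type cells, and Il1f9, Clec4d and Stfa1 are among the top genes of cluster 5. Knockout neutrophils had less of Cd63 (37.2 against 349.6 CPM, -3.23), Clec4d (1.49 against 257 CPM, 1 knockout UMI, -7.43, interval -12.74 to -4.94), Il1f9 (1 knockout UMI, -7.25, interval -12.56 to -4.76), Creg1 (3 knockout UMIs, -5.09, interval -7.38 to -3.51), Ccl6 (190.3 against 1242 CPM, -2.71) and Stfa1 (-2.65). Higher were Jund (260.2 against 55.7 CPM, 2.22), the adult globins Hba-a1 (5.53), Hbb-bs (5.03), Hba-a2 (4.42) and Hbb-bt (3.86), and Ppbp (1 wild-type UMI, 8.08, interval 5.59 to 13.39). In the knockout, Hbb-bs was at 4038 CPM in cluster 5 and 46.5 CPM in cluster 7, and Ppbp at 843 and 66.4 CPM. Only 18.7% of knockout and 10.0% of wild-type cells of the class had Hbb-bs. Doublets and RNA free in the droplets are not excluded. The split was 34 higher and 36 lower of 959, which scaling by the median of ratios (a shift of -0.16) took from 48.6% to 31.6% higher. Higher in knockout B cells were Jchain (5925 and 0 UMIs in knockout and wild type, at least 4774-fold higher), the plasma-cell factor Xbp1 (565 against 43.2 CPM, 3.71), Ly6a (5.69), Slpi (3.23), Txndc5 (2.74) and H2-Eb1 (2.48). Retnlg (-2.36), Lcn2 (-1.93), Camp (-1.27) and Ngp (-1.09), granule genes of neutrophils, were lower there with Cd72 (-1.18) and Serinc3 (-1.13). The class had 24 genes higher and 18 lower of 1019. By deposited class, and after a sort for CD41high CD42d+ cells negative for Ter119 and for B220, which B cells carry, knockout marrow had 3.88% B cells against 7.48%, 9.44% of cells deposited as Progenitor against 23.7% (median depths of 17469.5 and 3382.5 UMIs; cluster 1 of this class failed the marker check and is led by neutrophil granule genes), 30.7% macrophages against 24.8% and 6.70% dendritic cells against 2.36%, and the Neutrophil class made up 13.9% and 14.1%. The Eosinophil class, whose clusters 3 and 8 failed the marker check and have neutrophil granule genes among their top genes, made up 18.0% and 11.7%. That check held no eosinophil genes.

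Against fetal liver, adult wild-type cells had less RNA of megakaryocyte surface and alpha-granule genes and more RNA of neutrophil, B-cell and MHC class I genes. Chil3 and Retnlg are neutrophil granule genes, Vpreb3 and Ms4a1 belong to B cells, and Ccl5 to cytotoxic lymphocytes. On the fetal side stood embryonic Hbb-y, contractile Cald1 and Myl9, Slc6a4 and Alox12. Values are given as adult against fetal. Stage, tissue, transplant, sort and library go together in this comparison and cannot be told apart. The cell make-up differed too. The Megakaryocyte and Progenitor classes held 25.4% and 70.1% of fetal wild-type cells, and 10.0% and 23.7% of adult wild-type cells. Of 5751 genes compared, 817 were higher and 1644 lower in adult cells, while with median-of-ratios scaling (a shift of 0.32) the split was 944 and 978.

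Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564) had 11232 and 0 UMIs in adult and fetal wild type, at least 30566-fold higher in the adult. Retnlg (4574 against 0.952 CPM), S100a6 (2068 against 2.42 CPM, 9.74), Ifi27l2a (895 against 0.501 CPM, 10.80), S100a4 (10.88), H2-Q7 (10.88), Igll1 (2 fetal UMIs, 11.85, interval 9.99 to 14.90), Ly6d (1 fetal UMI, 13.48, interval 10.99 to 18.78) and Vpreb3 (1 fetal UMI, 14.43, interval 11.95 to 19.73) were among the higher genes. AW112010, Ms4a1 and Ccl5 had 0 fetal UMIs (at least 2740.3-, 1059- and 1042-fold). Hbb-y, Slc6a4 and the imprinted Ndn had 0 adult UMIs (at least 289-, 86.6- and 70.0-fold lower). Alox12 (0.818 against 147 CPM, -7.49), Cald1 (-8.07), Myl9 (1.43 against 144 CPM, -6.65), Ly6g6f (-7.04), Tgfb1i1 (-7.05) and Serpinb2 (-6.56) were lower in the adult, and so were Ank3 (1 adult UMI, -8.90, interval -14.20 to -6.42), Fhl2 (1 adult UMI, -8.24, interval -13.54 to -5.76) and Ppp1r14a (3 adult UMIs, -7.37, interval -9.65 to -5.83). All 19 megakaryocyte surface genes measured were lower in adult cells (median -4.58), as were all 13 fetal growth genes (median -3.72; Mest 1.33 against 68.4 CPM), all 3 embryonic globins and all 5 reported NF-E2 targets. Alpha-granule genes gave 1 higher and 17 lower of 21, median -3.25, percentile 0 (Pf4 1012 against 12588 CPM), proplatelet cytoskeleton genes 3 higher and 15 lower of 25, median -0.78, percentile 4.82 and dense-granule genes 2 higher and 8 lower of 18, median -0.20, percentile 81.2. Neutrophil genes (all 15, median 5.51; S100a8 7.40), B-cell genes (all 8), MHC class I genes (all 10, median 3.40; B2m 3102 against 310.5 CPM) and interferon genes (13 of 14, median 2.80) were higher. Given common weights, the 4 shared classes (Eosinophil, Erythrocyte, Megakaryocyte and Progenitor) left 522 genes higher and 1074 lower, with Retnlg at 7.72 and S100a6 at 6.57. Classes of the adult library alone, such as Macrophage, Neutrophil and BCell, were dropped by this step. It does not pair like cells, since Pf4 was at 86.3 CPM in the adult and 8993 CPM in the fetal Progenitor class.

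In the knockout pair, neutrophil and MHC class II genes were among the highest in adult cells. Stage, tissue, transplant, sort, library and cell make-up cannot be told apart here either. H2-Aa and Cd74 serve MHC class II presentation and were nearly absent from fetal knockout cells. Thbs1 and Timp3, of the alpha-granule list, and F2r were far lower in adult knockout cells. Of 5684 genes compared, 960 were higher and 1394 lower in adult knockout cells, and 1045 and 1031 with median-of-ratios scaling (a shift of 0.19). Chil3 (2580.0 against 0.168 CPM, 13.91), Cd74 (1285 against 0.279 CPM, 12.17), H2-Aa (3 fetal UMIs, 13.47, interval 11.92 to 15.75), Jchain (11.28), Retnlg (10.92), Ifi27l2a (10.91), S100a4 (10.90), S100a6 (10.11) and AW112010 (1 fetal UMI, 13.26, interval 10.78 to 18.57) were higher. H2-Q7, Slfn4 and Ms4a4b had 0 fetal UMIs (at least 3319.7-, 1238- and 1176-fold). Hba-x (0 and 18837 UMIs in adult and fetal knockout, at least 605-fold lower), Snrpn (0 adult UMIs, at least 105-fold), Thbs1 (13.9 against 851 CPM, -5.93), Timp3 (-5.40), F2r (14.6 against 552 CPM, -5.24), Gp1ba (2.22 against 101 CPM, -5.51) and Kdr (-6.38) were lower, as were Sardh (-6.89), Mcts2 (-6.81), Ank3 (-5.87), Sla2 (-5.37) and Lrrc32 (-6.04). All 18 megakaryocyte surface genes were lower here too (median -3.08). With the shared classes given common weights, 543 genes were higher and 853 lower, with Chil3 at 9.64, Cd74 at 3.88, Retnlg at 4.43 and Jchain at 1.86. The same 4 classes were weighted, so adult BCell, DC, Macrophage and Neutrophil cells do not enter these values.

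The knockout ratios of the tissues were weakly correlated. Thromboxane synthase Tbxas1 and the early hematopoietic factor Gata2 were lower in both, and platelet Ppbp and red-cell Alas2 and Gypa were higher in both. Myl9, which codes for a myosin light chain, and Alox12 had a larger ratio in adult marrow, a gap that was smaller without knockout-only cluster 12. Across 8307 genes the log2 ratios of fetal liver and adult marrow had a Pearson correlation of 0.27 and a Spearman correlation of 0.13, genes not being independent replicates. Without fetal cluster 7 and adult cluster 12, a step chosen after the values were seen, the Pearson correlation was 0.15, with 13 genes apart the same way and 2 opposite ways. Of 4002 genes compared in both, 12 were at least 2-fold higher in both (0.486 if the tissues were independent), 5 lower in both (0.225), and 0 went opposite ways.

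The 12 shared higher genes were Alas2 (4.61 in fetal liver and 3.37 in adult marrow), Hbb-y, Hbb-bt (2.29 in fetal liver and 3.20 in adult marrow, but level in fetal liver with common class weights), Gypa (2.08 in fetal liver and 3.81 in adult marrow), Pdzk1ip1 (3.12 in fetal liver and 4.31 in adult marrow), Ppbp, Clec4g, Cdk2ap1 (1.78 in fetal liver and 2.07 in adult marrow), Uba7 (1.41 in fetal liver and 2.57 in adult marrow), Cmas, Tnrc6c and Pepd. The 5 shared lower genes were Tbxas1 (-4.21 in fetal liver and -3.15 in adult marrow), Apoe (-2.19 in fetal liver and -1.30 in adult marrow), Gata2 (-1.89 in fetal liver and -1.31 in adult marrow), Ninj1 (-1.34 in fetal liver and -1.23 in adult marrow) and Cd63 (-1.07 in fetal liver and -1.31 in adult marrow). Ranked by the lower limit of the interval of the difference, the adult log2 ratio exceeded the fetal one most for Alox12 (by 5.43), Myl9 (by 5.15), Ppbp (by 4.53), Cald1 (by 5.56), Clu (by 4.42) and Clec4g (by 5.58). Without cluster 12 the adult ratios were 3.01 for Alox12, 1.79 for Myl9, 1.86 for Cald1, 4.04 for Clec4g, 2.23 for Ppbp and 2.16 for Clu, against 2.01 for Ppbp in fetal liver. By the matching upper limit, it was lower for Stfa1 (-0.52 in fetal liver and -3.18 in adult marrow), the glutamate-receptor related Grina (2.01 in fetal liver and -0.36 in adult marrow), Pou2f2 (2.29 in fetal liver and 0.17 in adult marrow), Thbs1 (0.25 in fetal liver and -1.65 in adult marrow), Cd24a (1.25 in fetal liver and -0.38 in adult marrow) and the metallothionein Mt1 (1.72 in fetal liver and 0.08 in adult marrow). Inside the Megakaryocyte class 39 genes were apart the same way in both tissues and 13 opposite ways, and without adult cluster 12 the counts were 9 and 3. These settings were chosen after the values were seen.

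The fetal pools differed in sex. Xist, expressed from the inactive X chromosome of females, was at 74.2 against 361 CPM in fetal knockout and wild type (-2.28) with Tsix at -1.96, and the Y-linked Eif2s3y (1.44), Ddx3y (1.53), Kdm5d (1.59) and Uty (1.74) were higher in the fetal knockout pool. In adult marrow Xist gave -0.58 and the 4 Y-linked genes lay between -0.43 and 0.09. These genes were kept out of the named set.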

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

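The test below was fixed before its values were seen, and only the choice to weigh it beside Parvb was made after the result was seen. Clec1b was picked out because its knockout ratio pointed opposite ways in the tissues: -2.31 in fetal liver and 0.96 in adult marrow, a difference of 3.27. Parvb was picked out for the same reason, with -2.36 and 0.65, a difference of 3.01. Neither difference was tested, since each tissue has 1 library per genotype. Both adult values hold cluster 12, the knockout-only cluster of the Megakaryocyte class.

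Parvb lies within 20 Mb of Nfe2 on chromosome 15, where the mutant chromosome could carry the sequence of another strain. Of the 129 fetal genes at least 2-fold apart, 2 (Parvb and Slc48a1, the latter named after its values were seen) lay within that distance, against 67 of 5139 compared genes with coordinates. That is 1.19 times as many (0.144 to 4.21), so linked strain variants and their absence cannot be told apart. No biological explanation was tested, and reads that carry variants would be needed to settle it.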

How the results depend on the processing

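Leaving out single clusters, comparing inside the Megakaryocyte class and leaving out the 5% of cells with the highest Scrublet score were chosen only after the results were seen; all other alternatives were fixed before. With no minimum of UMIs, 1913 genes (752 higher and 1161 lower) were at least 2-fold apart in fetal liver, 1292 (723 and 569) in adult marrow, 6389 between the stages in wild type and 6597 in knockout, since that setting lets in genes of few counts. With each cell's own CPM, 201 genes were apart in fetal liver (87 and 114), 32 the same way in both tissues (5 opposite ways), 455 in the fetal Megakaryocyte class (73 and 382), 1397 in the adult one (367 and 1030) and 43 in adult cluster 8. With common class weights, 1596 genes were apart between the stages in wild type and 1396 in knockout, over the 4 shared classes only. The correlation between tissues was 0.13 by Spearman, 0.12 inside the cells deposited as Progenitor (6 genes apart the same way and 2 opposite ways) and 0.15 without fetal cluster 7 and adult cluster 12 (13 and 2). The Progenitor name failed the marker check in 1 of 7 fetal and 1 of 2 adult clusters, and in fetal liver different clusters filled it in each genotype. Inside the Megakaryocyte class 39 genes were apart the same way and 13 opposite ways, or 9 and 3 without adult cluster 12. Without the 5% of cells with the highest Scrublet score, the fetal knockout Megakaryocyte share was 19.1%, cluster 8 had 14 genes apart, and Gadd45g there turned to -0.49. Without cluster 12, 66 genes were apart in the adult Megakaryocyte class, the adult surface-receptor list turned to -0.36, and the macrophage list in the adult Megakaryocyte class turned to -0.34, with 1 gene left in it. The Nfe2 log2 ratio was 0.000491 in the fetal cells deposited as Eosinophil and -0.77 in the fetal Megakaryocyte class. It went the other way in the fetal Erythrocyte class, with Nfe2 at 261 CPM in 469 knockout cells, mostly of cluster 7, and 64.8 CPM in 29 wild-type cells. In the fetal Progenitor class it was at 95.8 and 127 CPM. In adult classes the Nfe2 log2 ratio was 0.27 in B cells (0 and 6 UMIs, so without a direction), -0.15 in megakaryocytes, -0.68 in neutrophils and -0.66 in the cells deposited as Progenitor. Except for the minimum of UMIs and the clusters left out, the cause was not tested.

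Over the alternatives that could move a value, 105 counts, shares, correlations and levels stayed the same and 26 moved, as did 1348 and 289 ratios of single genes and 353 and 323 list medians, and 72 other class shares stayed the same. A count of genes stayed the same if its total stayed within 1.5-fold, so a changed split into higher and lower is not seen. The limit was 0.1 for correlations and list medians, and the counting interval for shares and single genes. Not counted are the use of all deposited barcodes and the minimum of 2000 UMIs, which left the cells as they were (the lowest had 2239 UMIs), and for single genes the minimums of UMIs, which leave a ratio as it is. Scrublet called only 39 cells. No single gene or list other than those named above turned. Depth limits the adult libraries most: at 4067.5 and 5905 UMIs per median cell, absence of a gene was bounded only at 0.307 and 0.290 CPM, and the 20 CPM minimum leaves out genes of low level in every library.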

Other observations

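The genes followed in the next 2 paragraphs, and the tests on shared barcodes, globin ratio, nearest cluster and Malat1, were chosen only after the result was seen. Embryonic Hbb-y was found in 69.5% of knockout and 8.48% of wild-type Progenitor cells, at 53.7 and 26.9 CPM, with median depths of 33631.5 and 24676.5 UMIs. In the Megakaryocyte class it was counted in 68.1% and 8.82% of cells, at 482 and 236 CPM. The gap was not particular to these classes: in the cells deposited as Eosinophil, Hbb-y was found in 49.3% of knockout and 6.19% of wild-type cells. Pf4 was found in 100% and 99.1% of them, so no fetal class gives a clean background share. Cluster 7 of the knockout library held Hbb-y at 15605 CPM, so RNA free in the droplets is not excluded. In cells of cluster 12, the erythroid cluster, Hbb-y was at 9599.6 CPM in knockout and 7.63 CPM in wild type, while Hbb-bs was at 20048 and 46740 CPM. Adult erythroid cells of cluster 15 had Hbb-bs at 100822 CPM in knockout and 46085 CPM in wild type, with Hbb-y at 6.53 and 0 CPM.

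Nuclear Malat1 split the megakaryocytes of both stages. In fetal liver its median was 124488 CPM in wild-type cells of cluster 10 (median 8804 UMIs) and 59307 CPM in knockout cells of cluster 7 (median 11800.5 UMIs), against 7229 CPM in wild-type cluster 6 and 8814 CPM in knockout cluster 4. Knockout cells of clusters 13 and 14 had medians of 151 and 132 CPM, and cluster 14 held the most Ppbp, at 53728 CPM. The eosinophil gene Epx was at 0 CPM in both genotypes in adult clusters 3 and 8, which are deposited as Eosinophil, and Prg2 was at 3.69 and 2.96 CPM in their wild-type cells and 0 CPM in their knockout cells.

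Fetal cluster 7, deposited as Erythrocyte, held 420 knockout cells, no wild-type cell, and both Pf4 (29762 CPM) and Hbb-y (15605 CPM). If red cells of cluster 12 as a whole had been mixed in, its ratio of Hbb-y to Hbb-bs should be that of cluster 12. It was 73.2 times as high (69.0 to 77.8, with 35.1 against 0.479), which argues against mixing with the average of cluster 12. The ratio cannot speak on RNA from Hbb-y-rich cells inside cluster 12 or from red cells outside it. Its mean profile was closest to wild-type cluster 10 (Spearman 0.851 over 7837 genes, against 0.578 for cluster 12, a difference of 0.273), so it may be a Malat1-rich state that wild-type cells also hold. Whether that state is living cells, naked nuclei or damaged cells stays open, and so does the source of its globin RNA. The biological explanation, an effect of the genotype on globin genes in megakaryocytes, was not tested.

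Adult cluster 12, with 113 knockout cells and none of wild type, held Ppbp (33242 CPM) together with embryonic Hbb-y (2333 CPM). Only 1 of its 113 barcodes was also a cell barcode of the fetal knockout library, which argues against reads passed between libraries. Its MHC class I sum was 29.1 times that of fetal knockout megakaryocytes (28.4 to 29.9; 16072 against 552 CPM), which argues against fetal cells carried over. Its median Malat1 was 0 times that of knockout cluster 6, with none in 78 cells (69.0%) against 2 of 34, so many of these droplets could be platelets or cell fragments. Whether the genotype, the transplant or the sort put them there was not tested.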
